A study of Mus musculus with 24 samples.

How the data were processed

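RNA from the urogenital sinus (UGS) of C57BL/6J mouse embryos was measured on 24 2-colour Agilent whole mouse genome arrays. The UGS is the embryonic endoderm tube and mesenchyme from which the prostate grows in males. Per the labels, pregnant females received 50 mg/kg dihydrotestosterone (DHT), the androgen that the enzyme 5-alpha-reductase makes from testosterone, or vehicle at 16 days post coitum (dpc). The UGS of their female embryos was taken 6 or 12 h later. A further set of pools came from untreated male and female littermates at 17.5 dpc, which the labels count as a 48 h point. The accessory ducts were dissected away, embryos were sexed by their gonads, and RNA from several embryos was pooled. Each pair of pools was amplified, labelled with Cy3 and Cy5 and hybridised directly against its partner, and once more with the dyes exchanged. There were 4 pairs of pools at 6 h (8 arrays), 3 at 12 h (6 arrays) and 5 of males against females (10 arrays).

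Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 7.5.1 and hold spot intensity in both channels, local background, and a background-corrected, dye-normalised log10 ratio of Cy5 over Cy3 that is limited to −2 and 2. The deposited series matrix holds 1 log2 ratio per probe and array, for 41174 probes. The medians of its columns ranged from −0.0112 to 0.0108, so each column was centred close to 0. How the authors centred those log2 ratios, and which spots they left out, is not stated. Its columns ran the same way as the scanner ratios on the arrays without dye swap and the opposite way on the swapped ones, so they were taken as already turned to DHT over vehicle and male over female. The series matrix was used as an alternative and not for the values in the results.

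Each array held 43790 spots, of which 41534 were not controls. The mean signals and median local backgrounds were taken from the scanner files and corrected in R 4.3.3 with limma 3.58.1 (normexp, offset 50), and the files were read with data.table version 1.17.8. Ratios were normalised within each array by loess with the control spots given no weight, and spots that the software marked as outliers were set to missing. Signs were turned so that a positive log2 ratio means more RNA in DHT than in vehicle pools, or in male than in female pools. Spots of 1 probe were averaged, and then the 2 dye-swapped arrays of each pair of pools, which share their RNA. The averages made 12 biological replicates. A probe was kept when at least 1 channel was well above background on at least 6 of the 24 arrays. Of 41174 probes, 35477 were kept, and the brightest probe of each gene stood for it, which gave 24717 genes. Probe names were matched to current symbols by accession for 21445 probes, by symbol for 5431 and by synonym for 4636, while 9662 kept the name in the file. No genome build was used, and positions of genes are not given.

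The 12 replicates were fitted together in limma with 1 coefficient per comparison, so that the 3 comparisons shared the estimate of spread of each gene, and the 3 differences between comparisons were contrasts of the same fit. Moderated tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over all genes, with 0.05 as the threshold. Any replicate was missing in 42 genes. SD is the standard deviation over replicates and SE the standard error from the fit.

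Gene lists, 29 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists and the 3 comparisons together. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare the list with other genes. A list is described as higher or lower by the test with the preset correlation. Of 597 list members, 572 were measured. There were 15 lists of themes, of which 1 is not described. The others were androgen-responsive genes known from adult prostate and prostate cancer cells; regulators of prostatic bud and urogenital sinus development; sex steroid receptors and steroid metabolism; the hedgehog, Notch and retinoic acid pathways; Wnt ligands, antagonists and targets; BMP, activin and TGF-beta signalling; FGF, IGF and EGF family growth factors; extracellular matrix; cell cycle; immediate early and stress response genes; circadian clock genes; and cholesterol and fatty acid synthesis. The 12 lists of markers covered epithelium, smooth muscle, fibroblast and mesenchyme, skeletal muscle, Wolffian and Mullerian ducts with seminal vesicle, gonad and adrenal, red blood cells, immune cells, endothelium, neurons and Schwann cells, cartilage and bone, and intestine. The 2 lists that check the labels were Y-linked genes, and Xist with X-linked genes that escape X inactivation.

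The lists, the fit, the alternatives and the rule for naming genes were set before the data were examined, except where the closing section says otherwise. By that rule, each comparison names up to 10 genes with the largest rise and 10 with the largest fall, among those past the threshold with 1 direction in every replicate and an informative symbol. It also names up to 4 members of each list past the threshold with the smallest p. Fkbp5, Srd5a2, Shh, Fgf10, Foxa1, Hoxb13 and Sox9 were among the genes always named, as were Xist, Ddx3y, Eif2s3y, Kdm5d and Uty between the sexes. Values of a few genes that the rule names, and of 1 list, are left out of the text, although counts of genes and lists include them. Each difference between comparisons names 5 genes each way, where as many passed. Genes from the lists of shared calls, and members of the lists that are given as examples of what did not pass, were named after their values were seen.

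Signals were low in relation to background. The median spot signal per array, before background correction, ranged from 102.3 to 151.1 in Cy3 and from 98.14 to 146.2 in Cy5. Median local backgrounds ranged from 51 to 62 and from 56 to 61. Between 67.5% and 82% of probes were well above background in Cy3 and between 71.1% and 80.5% in Cy5. The array of male-female replicate 1 with exchanged dyes had 1646 outlier-marked spots, and the other 23 had at most 219. The number of arrays limits the precision. Tested on simulated data with 24717 genes, the procedure recovered 89.6% of genes changed 1.5-fold at 6 h, 95.5% at 12 h and 98.5% between the sexes. At 2-fold it recovered 98.5% in each, and at 4-fold 100%. Unchanged genes made up 9 of 201, 13 of 209 and 9 of 207 calls. Noise was drawn separately for each gene, and every simulated change was larger than most real ones. The median absolute log2 ratio of the real calls was 0.248 at 6 h, 0.271 at 12 h and 0.264 between the sexes. These rates therefore do not describe the real calls, nor shifts that many genes of a pool share.

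Alternatives covered background correction, scaling, the scanner's own ratios, the series matrix, filters, the handling of several probes per gene, marked spots, the fit, weights, dye, extraction day, and leaving out each replicate. Overlaps were tested with Fisher's exact test, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. The comparisons were hybridised on different days, so hybridisation day and comparison cannot be told apart. Image extraction fell on 2 days at 6 h, on 1 at 12 h and on 3 between the sexes. The number of embryos per pool is not given.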

Results

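The prostate forms under androgen, and in the mouse its buds grow out of the UGS epithelium shortly before birth under signals from androgen-responsive mesenchyme. The series asked which UGS genes depend on androgen. Gene expression was compared within 12 pairs of RNA pools. In 4 pairs at 6 h and 3 pairs at 12 h, embryos exposed to DHT were set against embryos exposed to vehicle, all labelled female. In 5 pairs untreated males were set against females at 17.5 dpc. Each pair was measured on 2 arrays with exchanged dyes. The median spot signal per array, before background correction, was between 102.3 and 151.1 in Cy3 and between 98.14 and 146.2 in Cy5, and 24717 genes were tested. Across genes, which are not independent replicates, the 2 arrays of a male-female pair correlated at r = 0.39 to 0.762. The same correlation was −0.5 to −0.049 at 6 h and −0.197 to 0.163 at 12 h. The dye effect had an SD across genes of 0.133 at 6 h and 0.12 at 12 h, against 0.0906 and 0.102 for the ratio itself. Between the sexes the dye effect had an SD of 0.082 and the ratio 0.145.

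The 6 h comparison asked which genes of the female UGS respond early to DHT. Several developmental regulators were lower in the DHT pools. Gata3, a zinc-finger factor of the UGS and the urogenital ducts, fell together with Hoxa10 and Hoxa13, which pattern the caudal urogenital tract. Id1, a direct target of BMP signalling, Lef1, a nuclear partner of beta-catenin in Wnt signalling, and the receptor gene Notch1 were also lower. Egfr and Fgf18, a receptor and a ligand of growth factor pathways that act between epithelium and mesenchyme, were higher. Fkbp5, a common readout of androgen action, and the other genes of the androgen-responsive list did not pass the threshold. The 6 h vehicle pools of replicates 2 to 4 carried Y-linked RNA, as described below. Gata3, Hoxa10 and Id1 were higher in males, so male RNA in those pools would lower their 6 h ratios too.

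In limma 120 genes were higher and 283 lower at 6 h, 403 in all (29.8% higher), and 3525 genes had an unadjusted p under 0.05. The effects were small, with a median absolute log2 ratio of 0.248. Smoc2, a secreted calcium-binding matrix protein, fell by 0.68 on the log2 scale (SD 0.08, n = 4, adjusted p = 0.000393), and its second probe read −0.17. Gata3 fell by 0.49 (SD 0.13, adjusted p = 0.00228). Hnrnpa0, an RNA-binding protein, fell by 0.55 (SD 0.09, adjusted p = 0.0017) and Irf2bp2, a transcriptional corepressor, by 0.50 (SD 0.13, adjusted p = 0.00644). Pigt fell by 0.73 (SD 0.15, adjusted p = 0.0083) on a probe whose partner read 0.05. Id1 fell by 0.40 (SD 0.10, adjusted p = 0.0083), Lef1 by 0.43 (SD 0.16, adjusted p = 0.0158) and Notch1 by 0.32 (SD 0.15, adjusted p = 0.0202). D5Ertd121e, Wnk1 and Snrpd3 were lower by log2 ratios of −0.53, −0.52 and −0.51. The largest rises were Rhoj, a small GTPase of endothelial cells, at 0.58 (SD 0.17, adjusted p = 0.0316), Qpct at 0.47 (SD 0.15, adjusted p = 0.00544), Lrrn4cl at 0.43, Anpep at 0.40 and Cavin2 at 0.40. Zfp941, Pfas, Lrrc17, Adgre1 and Wfdc18 rose by 0.35 to 0.38.

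The Y-linked genes Eif2s3y and Ddx3y were among the largest falls at 6 h, at −1.31 (SD 0.97, adjusted p = 0.023) and −0.93 (SD 0.68, adjusted p = 0.0224), and Kdm5d was at −0.34. All pools were labelled female. In the vehicle pools of replicates 2, 3 and 4, Eif2s3y reached log2 signals of 8.66, 7.64 and 7.81. All lay above the 5.98 to 6.36 of the female pools at 17.5 dpc. Replicate 2 lay within the 8.51 to 9.01 of the male pools, and replicates 3 and 4 lay below that range. In replicate 1 the log2 ratios of Ddx3y and Eif2s3y were −0.07 and −0.04. Ddx3y was well above background on 0 of 8 DHT arrays and on 6 of 8 vehicle arrays, and its mean was at least 1.81-fold lower in the DHT pools; for Uty, at −0.25 (adjusted p = 0.0501), the bound was 1.16-fold. Xist had a log2 ratio of 1.07 in replicate 2 and −0.35 to 0.22 in the others. Aldh1a1, the named autosomal gene with the largest excess in males, fell by 0.67 (SD 0.44, adjusted p = 0.0236), with −1.14 in replicate 2 and −0.08 in replicate 1. Gata3 was lower in replicate 1 too, at −0.56, as were Smoc2 at −0.59 and Id1 at −0.46, and that replicate had the lowest mean of epithelial markers at 6 h, −0.524.

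**Figure D1:**
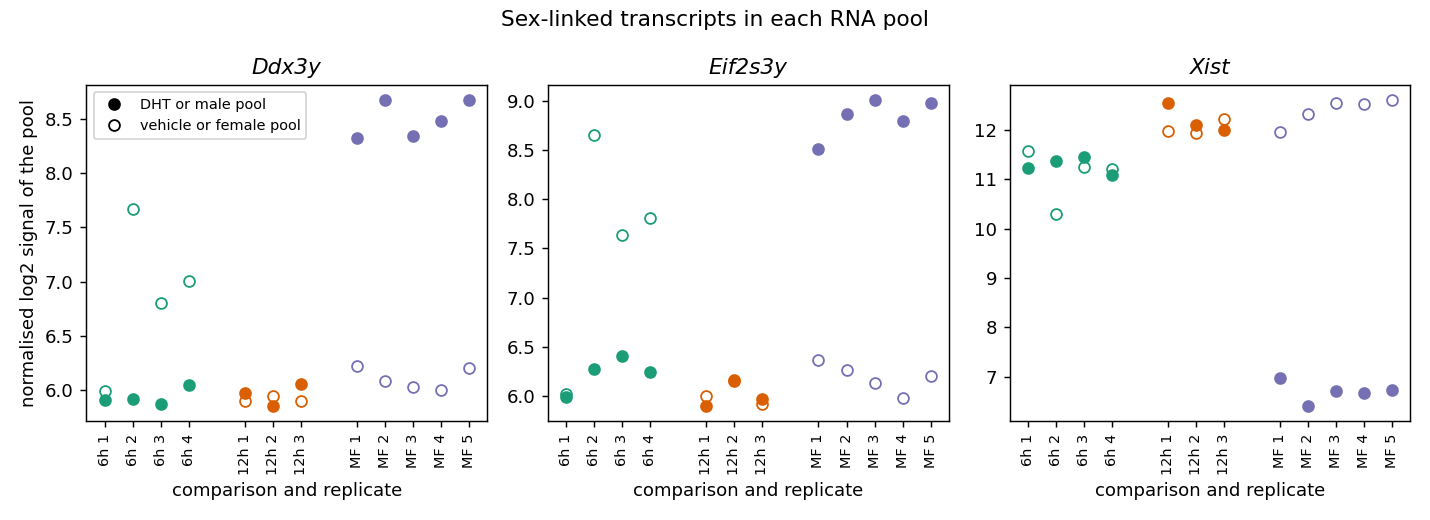
Normalised log2 signal (vertical axis) of Ddx3y, Eif2s3y and Xist in each RNA pool, by comparison and replicate (horizontal axis), with filled points for DHT or male pools and open points for vehicle or female pools. Eif2s3y lay at 7.64 to 8.66 in the 6 h vehicle pools of replicates 2 to 4, against 5.98 to 6.36 in the 5 female pools at 17.5 dpc and 8.51 to 9.01 in the male pools.

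By list, 8 of 29 passed at 6 h with the preset correlation and 0 with an estimated one in limma's camera, where 4 had an unadjusted p under 0.05; fry put 4 past the threshold. Regulators of prostatic bud and UGS development were lower (adjusted p = 1.63e-06, and adjusted p = 0.147 with an estimated correlation). Of 22 members 0 were higher and 3 lower over all genes (Gata3, Hoxa10 at −0.32, Hoxa13 at −0.23), and 19 did not pass, while 5 were lower adjusted over the list alone. The mean of the list, −0.241, −0.21, −0.073 and −0.048 in replicates 1 to 4, stood in the same order as the epithelial marker mean of −0.524, −0.422, −0.098 and 0.027. Sox9 (−0.31, adjusted p = 0.0704) and Shh (−0.29, adjusted p = 0.146) did not pass over all genes. The BMP, activin and TGF-beta list was lower (adjusted p = 0.00135, and adjusted p = 0.0668 with an estimated correlation), with 0 higher, 2 lower (Id1, and Inhba at −0.29) and 26 not past, and 5 lower adjusted over the list alone. The hedgehog list, lower at adjusted p = 0.0431 (adjusted p = 0.373 with an estimated correlation), had 0 of 17 members past over all genes in limma, 7 at an unadjusted p under 0.05, and 1 higher and 3 lower adjusted over the list alone. Cholesterol and fatty acid synthesis was lower (adjusted p = 2.15e-05, and adjusted p = 0.373 with an estimated correlation), with 0 higher, 1 lower and 22 not past over all genes, and 5 lower adjusted over the list alone. Y-linked genes were lower (adjusted p = 4.88e-06, and adjusted p = 0.0668 with an estimated correlation), 3 of 5 over all genes and 4 adjusted over the list alone.

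Epithelial markers were lower as a list at 6 h in camera with the preset correlation (adjusted p = 6.67e-09). The list did not pass with an estimated correlation (adjusted p = 0.373). The mean pairwise correlation of these markers within groups was 0.55, far above the preset, so the preset p is too small for this list. All 27 had negative log2 ratios; 0 passed singly over all genes in limma, 11 at an unadjusted p under 0.05, and 2 were lower adjusted over the list alone; their mean was −0.524, −0.422, −0.098 and 0.027 in replicates 1 to 4. Immune cell markers were higher (adjusted p = 0.000212, and adjusted p = 0.279 with an estimated correlation). Their mean was 0.129 with 13 of 16 positive, among them Cpa3 at 0.54 and Mrc1 at 0.31, and Ptprc, at 0.19, was the 1 member past over all genes, with 5 higher adjusted over the list alone. Smooth muscle markers were lower (adjusted p = 0.0434, and adjusted p = 0.673 with an estimated correlation), with Myocd at −0.45 the 1 of 17 past, both over all genes and adjusted over the list alone. Androgen-responsive genes did not pass as a list (adjusted p = 0.925); 0 of 23 members passed in limma, over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Fkbp5 was at 0.07. The other lists that did not pass were cell cycle (adjusted p = 0.055, Rrm2 lower at −0.31), retinoic acid (0.0722, with Aldh1a1), neuron and Schwann cell (0.155), skeletal muscle (0.188), endothelium (0.189), gonad and adrenal (0.282), intestine (0.313), Wnt (0.344, with Lef1), Xist with X-escape genes (0.525) and extracellular matrix (0.525). Immediate early genes (0.559) held Ier2 at −0.35 and Gadd45g at −0.21. Fibroblast and mesenchyme (0.581), circadian clock (0.599), ducts (0.752), steroid metabolism (0.752), cartilage and bone (0.93), Notch (0.93, with Notch1), FGF, IGF and EGF (0.93, with Egfr at 0.32 and Fgf18 at 0.29) and red blood cells (0.93) did not pass either. Foxa1 (−0.14), Hoxb13 (−0.07), Fgf10 (−0.05) and Srd5a2 (0.03) did not pass at 6 h. Median, mean and test differed in sign for the immediate early, fibroblast, Notch and FGF lists.

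The 6 h count fell to 92 genes with median centring (3 higher and 89 lower, 3.26% higher) and to 25 with the scanner's own ratios (1 higher and 24 lower, 4% higher), to 8 when the comparison was fitted alone, to 9 with the epithelial marker mean as covariate, to 3 with the Y-linked signal as covariate and to 1 with replicate 1 only (of the 403 genes, 0 in the last 2), which leaves 1 pair of pools, 3 alternatives chosen after seeing the data, and to 19 without replicate 1 and 13 without replicate 2. The Y-linked covariate fit takes the 6 h ratio at no Y-linked signal, which only replicate 1 came near. Its count therefore cannot separate male RNA from lost precision. Smoc2 lost its call under 2 of 24 other settings and Gata3 under 3, while Ptprc lost it under 14.

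The 12 h comparison asked the same question at a later time. The genes that rose were of several kinds. Nt5e encodes the surface enzyme CD73 that makes adenosine, Mkx is a homeobox factor of tendon and connective tissue, and Wif1 is a secreted Wnt inhibitor. Epha3 and Slitrk6 are surface proteins of neural and mesenchymal cells, Col4a6 is a basement membrane collagen, and Klf15 is a transcription factor induced by steroid hormones in several tissues. Wnt5b, a Wnt ligand, and Pcdh8, a protocadherin, fell.

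In limma 28 genes were higher and 43 lower at 12 h, 71 in all (39.4% higher), with a median absolute log2 ratio of 0.271, and 3479 genes had an unadjusted p under 0.05. Nt5e rose by 1.06 (SD 0.27, n = 3, adjusted p = 0.0264), or 2.08-fold, on a probe whose partner read 0.06. Mkx rose by 0.90 (SD 0.24, adjusted p = 0.0264), Epha3 by 0.74 (SD 0.11, adjusted p = 0.0264) and Slitrk6 by 0.52 (SD 0.07, adjusted p = 0.0264). Wif1 rose by 0.58 (SD 0.08, adjusted p = 0.0417), Klf15 by 0.57 (SD 0.05, adjusted p = 0.0498) and Lmcd1 by 0.52 (SD 0.14, adjusted p = 0.0375). Col4a6, Abi3bp and Setbp1 rose by 0.47, 0.43 and 0.42, and Gadd45g by 0.31 (adjusted p = 0.035). The falls were smaller. Pcdh8 fell by 0.33 (SD 0.06, adjusted p = 0.0264), Gna14 by 0.33 (SD 0.09, adjusted p = 0.0498) and Wnt5b by 0.28 (SD 0.11, adjusted p = 0.0475), and Lypd1, Lix1, Gatc, Pnma3, Aqp6, Ccdc138 and Septin14 had log2 ratios of −0.30 to −0.25. Of the 71 genes, 19 were in the dimmest quartile of brightness.

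By list, 10 of 29 passed at 12 h with the preset correlation and 0 with an estimated one in limma's camera, where 2 had an unadjusted p under 0.05; fry put 2 past the threshold, androgen-responsive genes among them. Androgen-responsive genes were higher (adjusted p = 0.018, and adjusted p = 0.147 with an estimated correlation). Of 23 members 0 passed over all genes in limma and 10 had an unadjusted p under 0.05, with 6 higher and 1 lower adjusted over the list alone, among the largest Errfi1 at 0.35 (adjusted p = 0.0848) and Fkbp5 at 0.30 (SD 0.06, adjusted p = 0.0873). Regulators of prostatic bud and UGS development were higher (adjusted p = 0.00228, and adjusted p = 0.367 with an estimated correlation), 0 of 22 over all genes in limma, 8 at an unadjusted p under 0.05 and 4 adjusted over the list alone. Its means of 0.061, 0.132 and 0.19 in replicates 1 to 3 stood in the same order as the epithelial means of −0.055, 0.329 and 0.606. Shh, the epithelial hedgehog ligand of budding, was at 0.49 (SD 0.16, adjusted p = 0.0769) and Foxa1 at 0.35 (adjusted p = 0.279), without passing. Cell cycle genes were lower (adjusted p = 4.88e-06, and adjusted p = 0.373 with an estimated correlation) by a mean of −0.087, 0 of 32 over all genes in limma, 8 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Cholesterol and fatty acid synthesis was lower (adjusted p = 0.0434, and adjusted p = 0.702 with an estimated correlation), 0 of 23 over all genes or adjusted over the list alone in limma and 3 at an unadjusted p under 0.05.

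Epithelial markers were higher as a list at 12 h in camera with the preset correlation (adjusted p = 4.84e-08). The list did not pass with an estimated correlation (adjusted p = 0.406). The preset p is too small for these markers, as at 6 h. All 27 were positive and 0 passed singly in limma, over all genes or adjusted over the list alone, with 11 at an unadjusted p under 0.05; the means were −0.055, 0.329 and 0.606 in replicates 1 to 3. Skeletal muscle markers were higher (adjusted p = 0.00097, and adjusted p = 0.702 with an estimated correlation) with means of 0.05, 0.356 and 0.706; 0 of 21 passed in limma and 2 had an unadjusted p under 0.05. Red blood cell markers (adjusted p = 0.000837, and adjusted p = 0.392 with an estimated correlation; 4 of 10 lower adjusted over the list alone), endothelium (adjusted p = 0.018, and adjusted p = 0.647 with an estimated correlation) and ducts (adjusted p = 0.0434, and adjusted p = 0.373 with an estimated correlation) were lower. The lists that did not pass were neuron and Schwann cell (adjusted p = 0.107), circadian clock (0.107; 3 higher adjusted over the list alone), immediate early genes (0.171, with Gadd45g), gonad and adrenal (0.296), Xist with X-escape genes (0.344), smooth muscle (0.434), FGF, IGF and EGF (0.559), immune cells (0.617), Notch (0.662), intestine (0.752), fibroblast and mesenchyme (0.752), steroid metabolism (0.752), Wnt (0.925, Wif1 higher and Wnt5b lower), hedgehog, retinoic acid and BMP (0.93 each), extracellular matrix (0.984), Y-linked genes (0.991) and cartilage and bone (0.999). Srd5a2 (0.32), Fgf10 (0.25), Sox9 (0.16) and Hoxb13 (0.16) did not pass at 12 h. Median, mean and test differed in sign for the Notch, fibroblast, Wnt, retinoic acid, BMP, matrix and cartilage lists.

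No gene passed at 12 h in limma without background correction, with the series matrix, with the comparison fitted alone or without any 1 of the 3 replicates, while 2636 to 3038 genes had an unadjusted p under 0.05. With median centring 18 genes were higher and 3 lower (85.7% higher); Mkx, Epha3, Nt5e, Slitrk6 and Wif1 each lost the call under 8 of 21 other settings.

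**Figure D2:**
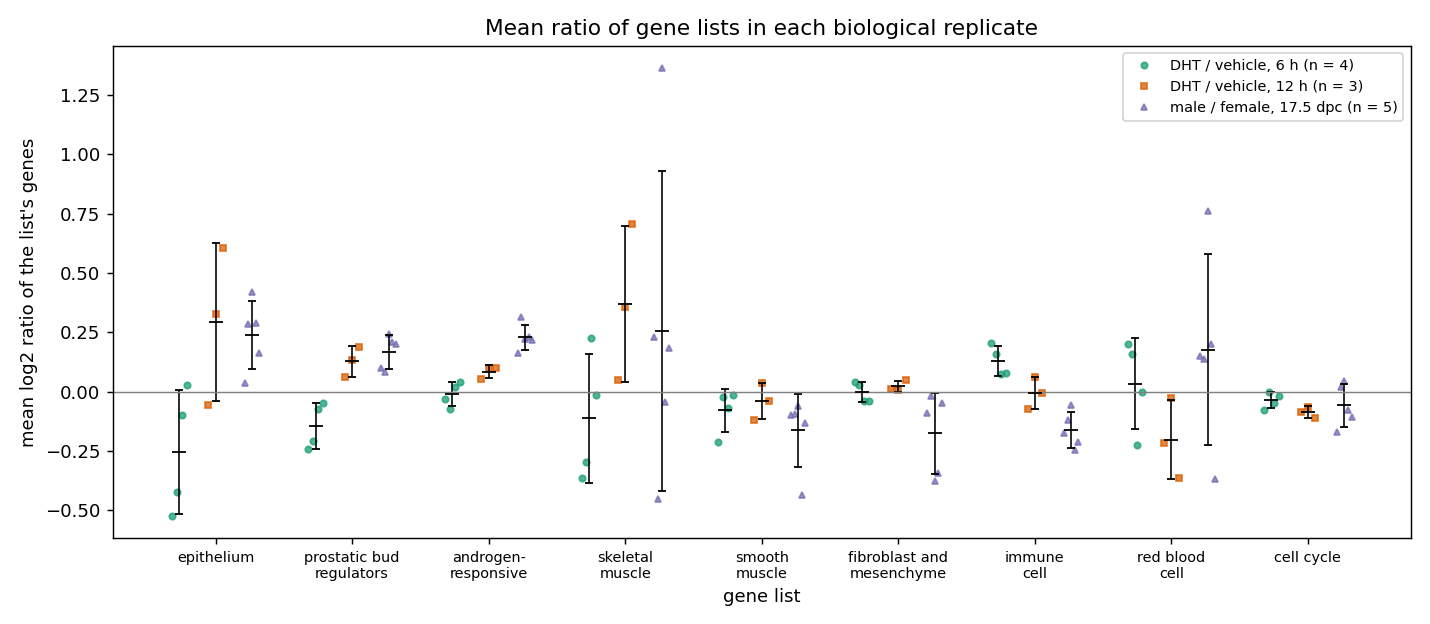
Mean log2 ratio (vertical axis) of 9 gene lists (horizontal axis) in the 3 comparisons, positive where DHT exceeded vehicle or males exceeded females; points are replicates and bars the mean and SD. The epithelial mean ran from −0.524 to 0.027 at 6 h, from −0.055 to 0.606 at 12 h and from 0.038 to 0.419 between the sexes, and the skeletal muscle mean ran from −0.454 to 1.363 between the sexes.

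The male-female comparison asked which genes differ in the UGS between the sexes when prostatic buds form. Several genes tied to budding or to androgen action were higher in males. Shh, the ligand by which the epithelium signals to mesenchyme, Sox9, Foxa1, Wif1 and Srd5a2, the 5-alpha-reductase of the urogenital tract, were all higher. So were the retinaldehyde dehydrogenases Aldh1a1 and Aldh1a3, which make retinoic acid. Females had more RNA of Esr1, the oestrogen receptor, of Amhr2 and Wnt7a, which act in the Mullerian duct, and of the stromal genes Col8a1, Dkk2 and Inhba.

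In limma 920 genes were higher and 953 lower in males, 1873 in all (49.1% higher). More than 2-fold differences were seen in 48 genes higher and 19 lower in males, and 4569 genes had an unadjusted p under 0.05. Sex-linked genes followed the labels. Xist, the transcript of the inactive X chromosome, fell by 5.69 in males (SD 0.39, n = 5, adjusted p = 3.42e-09), or 51.5-fold, while Eif2s3y rose by 2.65 (SD 0.30, adjusted p = 7.64e-06), Ddx3y by 2.38 (SD 0.19, adjusted p = 1.16e-06) and Kdm5d by 0.51. In the female pools Eif2s3y was well above background on 2 of 10 arrays and Ddx3y on 3 of 10, so their sizes are pulled towards 0. Uty was at least 1.59-fold higher in males, as it was well above background on 10 of 10 male and 0 of 10 female arrays. The Y-linked list was higher (adjusted p = 6.67e-09; 4 of 5 members) and the list of Xist with X-escape genes lower (adjusted p = 6.67e-09; 5 of 8 lower, with Eif2s3x at −0.65 but 0.25 with the mean of its probes, Pbdc1 at −0.44 and Ddx3x at −0.29); these were the 2 list calls of the study that held with an estimated correlation, at adjusted p = 0.0377 each.

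Aldh1a1 rose by 2.49 (SD 0.16, adjusted p = 1.88e-07), or 5.64-fold, Nt5e by 1.95 (SD 0.15, adjusted p = 3.8e-07) and Aldh1a3 by 1.93 (SD 0.43, adjusted p = 1.41e-05). Cyp1b1, an oxidase of retinoids and oestrogens, rose by 1.69, and Sult1e1, which sulphates oestrogens, by 1.67 (SD 0.41, adjusted p = 5.6e-06). The tight junction gene Cldn8, the cadherin Cdh16, Clu, and Mmp7, a matrix protease of glandular epithelium, rose by 1.68, 1.67, 1.66 and 1.60, and Wif1 by 1.53 (SD 0.19, adjusted p = 1.88e-07). Esr1 fell by 2.35 (SD 0.30, adjusted p = 1.97e-07), or 5.11-fold, and by 1.21 with the mean of its probes. Other probes of several genes read less than the brightest: −0.06 for Esr1, 0.00 for Cyp1b1, 0.55 for Aldh1a3, 0.10 for Nt5e, 0.04 for Sox9 and, among 4 for Xist, −0.26. Col8a1 fell by 1.74, Pnliprp1 by 1.42, Wfdc2 by 1.27, Dkk2, a Wnt antagonist of the mesenchyme, by 1.21 (SD 0.35, adjusted p = 8.02e-06) and Crabp1, which binds retinoic acid in the cytoplasm, by 1.18 (SD 0.38, adjusted p = 1e-05). Cstdc6, Stfa3 and Csta2, members of 1 closely similar stefin family whose probes were not checked for cross-hybridisation, fell by 2.18, 1.37 and 1.36.

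Androgen-responsive genes were higher as a list (adjusted p = 0.00228, and adjusted p = 0.0668 with an estimated correlation). Of 23 members 9 were higher, 2 lower and 12 not past, with 10 higher and 6 lower adjusted over the list alone; the mean was 0.229 and the median 0.04. Sgk1 rose by 1.16 (SD 0.05, adjusted p = 4.29e-07), Errfi1 by 0.72 and Fkbp5 by 0.71 (SD 0.17, adjusted p = 3.97e-06), and Ndrg1 fell by 0.45. Regulators of prostatic bud and UGS development were higher (adjusted p = 8.36e-05, and adjusted p = 0.275 with an estimated correlation), 9 higher, 1 lower and 12 not past, and 9 and 2 adjusted over the list alone. Among them Sox9 rose by 0.79 (SD 0.20, adjusted p = 1.36e-05), Gata3 by 0.62 (SD 0.09, adjusted p = 4.82e-06), Shh by 0.60 (SD 0.19, adjusted p = 0.000535), Foxa1 by 0.50, Hoxa10 by 0.28, Hoxb13 by 0.22 and Fgf10 by 0.20 (SD 0.14, adjusted p = 0.0161). The list of steroid receptors and metabolism did not pass (adjusted p = 0.0688; 3 higher, 2 lower, 14 not past): Sult1e1, Srd5a2 at 0.46 and Cyp7b1 at 0.40 were higher, and Esr1 was among the lower.

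The retinoic acid list did not pass (adjusted p = 0.0688), with a mean of 0.252 and 6 members higher, 1 lower and 11 not past. Higher were Aldh1a1, Aldh1a3, the degrading enzyme Cyp26a1 at 0.68, Dhrs3 at 0.38, Rdh10 at 0.37 and Aldh1a2 at 0.28, and Crabp1 was lower. Wnt genes went both ways (adjusted p = 0.752; 7 higher, 9 lower, 20 not past; 8 and 10 adjusted over the list alone). Wnt4 rose by 0.94 (SD 0.19, adjusted p = 4.94e-06), Sp5 by 0.79, Rspo3 by 0.62, Sfrp2 by 0.56 and Wnt9b by 0.51, while Rspo2 fell by 1.04, Rspo1 by 0.77 and Wnt7a by 0.77 (SD 0.08, adjusted p = 1.07e-06). BMP, activin and TGF-beta genes were also split (adjusted p = 0.93; 7 higher, 7 lower, 14 not past; 7 and 7 adjusted over the list alone). Fst, which binds activin, rose by 0.46, Id3 by 0.44, Id2 by 0.38 and Id1 by 0.32. Inhba, an activin subunit, fell by 0.80 (SD 0.18, adjusted p = 2.34e-06), Tgfbi by 0.69 and the BMP antagonist Grem1 by 0.36. In the FGF, IGF and EGF list (adjusted p = 0.517; 8 higher, 6 lower, 22 not past; 9 and 10 adjusted over the list alone), Igfbp2 rose by 1.02, Etv4, a transcriptional target of FGF signalling, by 0.68 (SD 0.11, adjusted p = 3.07e-07), Igfbp6 by 0.64, and Fgfr2 and Fgfr3 by 0.46 each. Fgf18 fell by 0.49 and Igf1 by 0.39. Hedgehog genes (adjusted p = 0.999; 3 higher, 3 lower, 11 not past) held Shh, Ptch1 at 0.27 and Hhip at 0.24 above 0, and Gas1 at −0.42, Sufu at −0.18 and Gli2 at −0.15 below.

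Extracellular matrix genes were lower in males (adjusted p = 0.0123, and adjusted p = 0.702 with an estimated correlation), 3 higher, 11 lower and 33 not past, and 4 and 16 adjusted over the list alone. Their means were −0.198 and −0.282 in replicates 3 and 4 and −0.052, 0.049 and 0.087 in replicates 1, 2 and 5. Mmp7 and Spp1 (0.62) were higher, and Col1a1 (−0.67), Loxl1 (−0.57) and Mmp16 (−0.51) lower. Fibroblast and mesenchyme markers were lower (adjusted p = 0.0116, and adjusted p = 0.414 with an estimated correlation), 1 higher, 6 lower and 8 not past, and 2 and 7 adjusted over the list alone, with Prrx1 at −0.62 and Twist2 at −0.36, and with means of −0.375 and −0.343 in replicates 3 and 4 against −0.092, −0.017 and −0.049 in the others. Smooth muscle markers were lower (adjusted p = 0.000309, and adjusted p = 0.373 with an estimated correlation), 0 higher and 6 of 17 lower, 10 adjusted over the list alone, with Myh11 at −0.47, Myocd at −0.38, Pgm5 at −0.34 and Synpo2 at −0.23. Epithelial markers were higher with the preset correlation (adjusted p = 6.38e-06), which is too low for them, but did not pass with an estimated one (adjusted p = 0.566). Singly, 11 were higher, 1 lower and 15 not past, and 12 and 1 adjusted over the list alone. Cldn4 and Krt7 rose by 0.64 each and Epcam by 0.45, and Krt17 fell by 0.72. Immune markers were lower (adjusted p = 1.44e-06, and adjusted p = 0.147 with an estimated correlation), 5 of 16 over all genes and 6 adjusted over the list alone, with Lyz2 at −0.53, C1qc at −0.36, Tyrobp at −0.27 and C1qa at −0.19. Endothelial markers were lower (adjusted p = 0.018, and adjusted p = 0.647 with an estimated correlation), 2 of 16 over all genes and 3 adjusted over the list alone, Sox17 at −0.98 and Sox18 at −0.12, which lost its call under 13 of 23 other settings. The median of the list was −0.044 and its mean −0.114, with means of −0.119, 0.002, −0.244, −0.23 and 0.019 in replicates 1 to 5. Skeletal muscle markers were higher (adjusted p = 0.00852, and adjusted p = 0.744 with an estimated correlation), 0 of 21 singly in limma and 4 at an unadjusted p under 0.05, with replicate means from −0.454 to 1.363. Cell cycle genes were lower (adjusted p = 0.00688, and adjusted p = 0.656 with an estimated correlation), although the 1 member of 32 past over all genes, E2f1 at 0.16, was higher.

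The other lists did not pass between the sexes. Notch (adjusted p = 0.0725) had Dll1 lower at −0.33. Cholesterol and fatty acid synthesis (0.107) had Elovl6 at −0.20 and Srebf1 at −0.13 lower. Immediate early genes (0.925; 3 higher, 1 lower) had Gadd45g at 0.34, Ccn1 at 0.21 and Ier3 at 0.17 higher and Jund at −0.28 lower. The ducts list (0.93; 2 higher, 2 lower, 10 not past; 3 and 2 adjusted over the list alone) had Calb1 at 1.53 and Wnt9b higher, and Amhr2 at −1.08 and Wnt7a lower; its mean of 0.024 became −0.069 with the scanner's own ratios. As the ducts list holds both Wolffian and Mullerian markers, opposite moves cancel in its test. The test therefore cannot show that duct tissue was even between the sexes. Cartilage and bone (0.925) had Col9a3 at 0.24 higher and Col2a1 at −0.41 lower. Neuron and Schwann cell (0.141), red blood cells (0.151), circadian clock (0.236), gonad and adrenal (0.517) and intestine (0.617) did not pass. Median, mean and test differed in sign for the Wnt, immediate early, ducts and BMP lists.

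**Figure D3:**
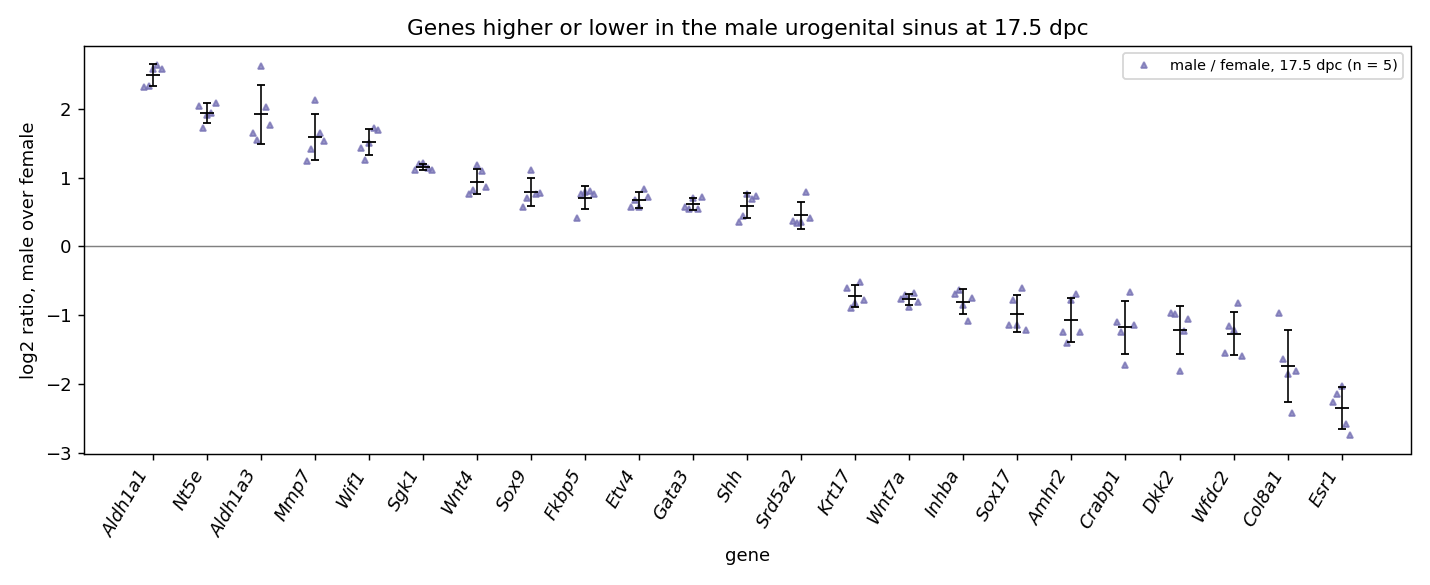
Log2 ratio of males over females (vertical axis) for 23 genes (horizontal axis) at 17.5 dpc, with points for the 5 pairs of pools and bars for the mean and SD. Aldh1a1 had the largest rise among them, at 2.49, and Esr1 had a mean of −2.35, with every pair on 1 side of 0 for both.

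With median centring 552 genes were higher and 941 lower in males (37% higher), and 869 genes passed when the comparison was fitted alone, 1143 without replicate 4 and, in an alternative chosen after seeing the data, 1038 with the epithelial marker mean as covariate, 935 of them among the 1873.

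Differences between the comparisons asked whether responses at 6 h, 12 h and between the sexes differed in size. Mkx, Epha3, Wif1 and Col4a6 rose at 12 h and had negative estimates at 6 h, where Col4a6 passed the threshold as lower (−0.34, adjusted p = 0.0366) and the other genes did not pass. These genes were also higher in males, by 1.43, 0.94, 1.53 and 0.87. Male RNA in the 6 h vehicle pools would therefore lower their 6 h ratios too. Rhoj rose at 6 h and had a negative estimate at 12 h. Aldh1a1 and Esr1 separated the sexes far more than DHT did at either time.

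Between 12 h and 6 h 24 genes differed upward and 4 downward, 28 in all (85.7% higher), with 3563 at an unadjusted p under 0.05. Mkx differed by 1.09 (SE 0.15, adjusted p = 0.0247), Epha3 by 0.99 (SE 0.13, adjusted p = 0.0247), Col4a6 by 0.81 (SE 0.11, adjusted p = 0.0247), Wif1 by 0.82 (SE 0.12, adjusted p = 0.0462) and Cbr2, a carbonyl reductase, by 0.82 (SE 0.14, adjusted p = 0.0478). Rhoj differed by −1.18 (SE 0.18, adjusted p = 0.0462), from 0.58 at 6 h to −0.60 at 12 h, Pcdh8 by −0.43 and Mpv17l by −0.41. Gata3 (0.72, adjusted p = 0.0133) and Id1 (0.61, adjusted p = 0.0247) differed too, but Shh (0.78, adjusted p = 0.0566) did not pass. Without background correction 11 genes passed, all higher (100%), and with the scanner's ratios 0 in limma, with 2840 at an unadjusted p under 0.05. Limma also called 0 without any 1 of the 12 h replicates or without 6 h replicate 2, and, in alternatives chosen after seeing the data, with 6 h replicate 1 only or the Y-linked or epithelial covariate, with 2425 to 3485 at an unadjusted p under 0.05.

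Males minus females differed from the 6 h response in 1709 genes, 867 upward and 842 downward, with Aldh1a1 at 3.17 (SE 0.17, adjusted p = 1.67e-06), Cldn8 at 2.26, Aldh1a3 at 2.07 and Eif2s3y at 3.96 upward. Ddx3y passed upward too, but without a size, since its signal at 6 h was a bound. Esr1 at −2.23 (SE 0.17, adjusted p = 1.9e-05), Xist at −5.89, Cstdc6 at −2.37, Stfa3 at −1.61 and Csta2 at −1.60 were downward. Against the 12 h response 200 genes differed upward and 208 downward, 408 in all. Aldh1a1 was at 2.08 (SE 0.19, adjusted p = 0.000382), Cdh16 at 1.95 and Gsta3 at 1.70. Eif2s3y and Ddx3y passed upward without a size, as both were near background at 12 h. Esr1 was at −2.03 (SE 0.19, adjusted p = 0.000382), Xist at −5.85 and the stefins Cstdc6, Stfa3 and Csta2 at −3.29, −2.56 and −2.31. Sox9 also differed, by 0.64 (adjusted p = 0.0156), and Fkbp5 by 0.41 (adjusted p = 0.0401). The 6 h side of the difference from 6 h carries the Y-linked signal of the vehicle pools: Eif2s3y differed by 3.96 where the sexes alone differed by 2.65. Most female arrays were near background for Eif2s3y, so both sizes are pulled towards 0. Aldh1a1, an autosomal gene, differed by 3.17 where the sexes differed by 2.49, which restates its fall at 6 h. The 1709 became 815 with median centring, 1110 with the scanner's ratios, 860 without 6 h replicate 2 and 969 without 6 h replicate 1. In alternatives chosen after seeing the data they became 148 with the Y-linked signal and 278 with the epithelial marker mean as covariate, and 83 with 6 h replicate 1 only, where 1 pair of pools stands for 6 h and is assumed to vary like the others. With median centring the split against 12 h was 124 higher and 238 lower (34.3% higher). Without 12 h replicate 1 the count was 135. In all 3 differences, hybridisation day and, for the sexes, age cannot be told apart from the comparison.

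The overlap asked whether the genes that DHT raised in females were those higher in males. Nt5e, Mkx, Wif1, Epha3, Slitrk6, Klf15, Lmcd1, Col4a5 and Col4a6 were higher in both. Col4a5 and Col4a6 lie next to each other on the X chromosome and encode chains of 1 basement membrane collagen. Synpr, a synaptic vesicle protein, was the only gene higher in all 3 comparisons, at 0.27, 0.40 and 0.81, and none was lower in all 3.

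Of the 28 genes higher at 12 h, 19 were higher in males, where 1.04 would be shared by chance (odds ratio 55.7; Fisher's exact p = 2.94e-21, adjusted p = 3.53e-20 over 12 overlaps). They were the 9 named above with Ralgps2, Rasl11b, Gadd45g, Abi3bp, Synpr, Lrrk1, Pla2g4a, Acot1, Setbp1 and a transcript without a gene name. Another 3 of the 28 were lower in males (1.08 by chance; adjusted p = 0.138). Among the 43 lower at 12 h, Kcnh2, Wnt5b, Pcdh8 and Lypd1 were lower in males (1.66 by chance; adjusted p = 0.138). Of the 920 genes higher in males, 711 had a positive and 209 a negative log2 ratio at 12 h (median 0.079), against 325 and 595 at 6 h (median −0.039). At 6 h, genes lower with DHT were shared with genes lower in males (25, against 10.9 by chance; adjusted p = 0.000496) and with genes higher in males (20, against 10.5; adjusted p = 0.019). Genes higher with DHT were shared with genes lower in males (17, against 4.63; adjusted p = 2.18e-05) and with genes higher in males (8, against 4.47; adjusted p = 0.138). The 6 h and 12 h calls shared 1 gene in the same direction, Synpr, and 2 that were lower at 6 h and higher at 12 h (0.321 by chance, adjusted p = 0.0974). The 3 comparisons shared the spread of each gene, so a gene of small spread is more readily called in each. The numbers by chance and Fisher's exact test leave this out and take genes as independent. RNA of male embryos in the 6 h vehicle pools would also favour opposite directions between 6 h and the sexes. Across genes, which are not independent replicates, Pearson's r was −0.059 between 6 h and 12 h (Spearman −0.013), −0.207 between 6 h and the sexes (−0.139; Pearson −0.071 with 6 h replicate 1 only and −0.092 with median centring) and 0.191 between 12 h and the sexes (0.105). With the series matrix no gene passed at 12 h in limma, so 0 were shared, with 2636 at an unadjusted p under 0.05, and with median centring the r of 12 h with the sexes was 0.076.

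**Figure D4:**
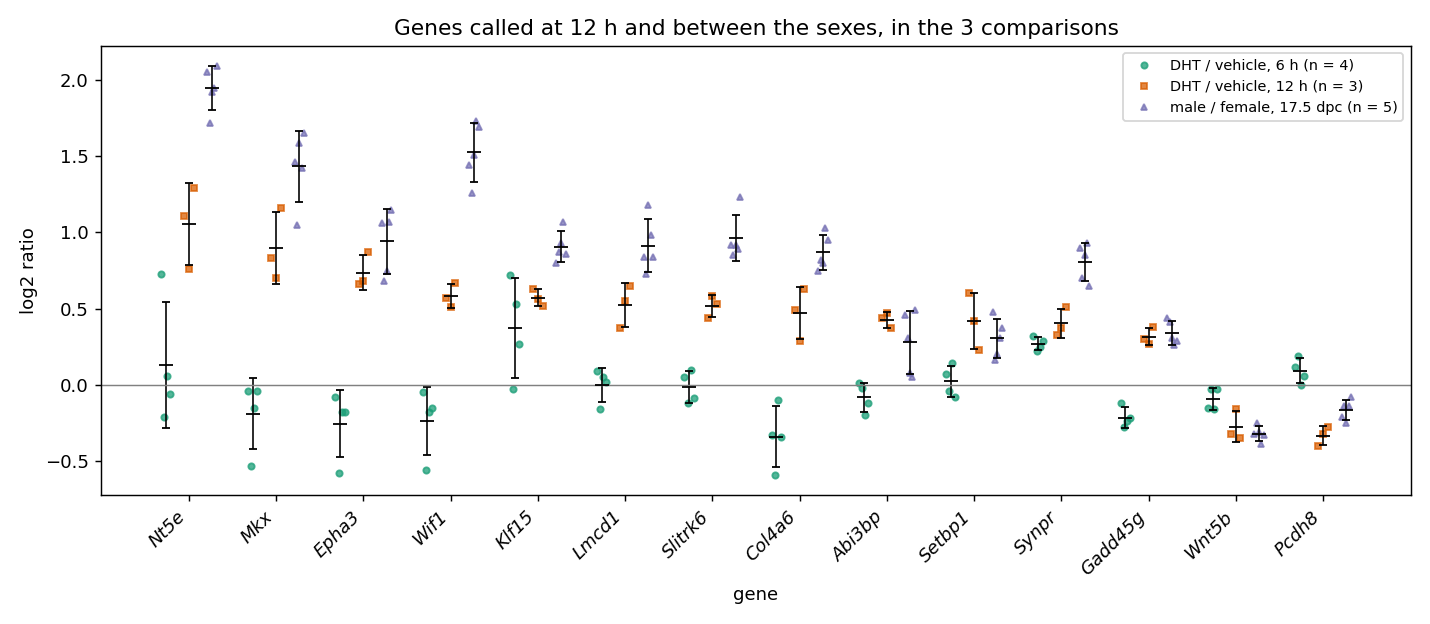
Log2 ratio (vertical axis) of 14 genes (horizontal axis) in the 3 comparisons, with points for each pair of pools and bars for the mean and SD; positive values mean more RNA in DHT or male pools. Nt5e had means of 0.13 at 6 h, 1.06 at 12 h and 1.95 between the sexes, and Mkx had −0.19, 0.90 and 1.43.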

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

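Chosen after the result was seen were the tests of the Y-linked signal in vehicle pools against the female pools, of its excess over those pools, of the correlation of epithelial markers, and of how many replicates went the way of their time point. The fits with marker means as covariates were alternatives chosen after seeing the data, with their predictions for the genes shared by 12 h and males written before those values were seen. The other tests in this part, and the splits of the replicates, were written before their results were seen.

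Lower Y-linked RNA in the DHT pools at 6 h came from the vehicle side. The values below argue against vehicle pools of female embryos only in replicates 2 to 4. Ddx3y and Eif2s3y were well above background there on 2 of 2 vehicle arrays of each replicate. The vehicle pools of 3 replicates (2 to 4) lay above the highest of the 5 female pools at 17.5 dpc for both Ddx3y and Eif2s3y, and in those 3 the autosomal genes more than 2-fold higher in males (46 genes) were lower in DHT pools, with medians of −0.51, −0.16 and −0.21, against 0.02 in replicate 1, as RNA of male embryos in the vehicle pools would give. A response of Y-linked genes to DHT with no male RNA in any pool is argued against, since the smallest excess over the highest female pool was 0.58 for Ddx3y, where the 5 female pools had an SD of 0.1, and 1.28 for Eif2s3y, with an SD of 0.14. The share of male RNA stays open. With none assumed in the DHT pools, it was 80.1% from Eif2s3y, 55.7% from Ddx3y and 52.4% from Xist in replicate 2. These genes gave −9.4% to 37.7% in replicates 3 and 4, and Xist gave −27.3% in replicate 1. The assumption was not tested, and Eif2s3y was well above background on 6 of 8 DHT arrays. Gata3, Smoc2 and Id1 were lower in replicate 1 too, where no male signal was seen but the epithelial mean was the lowest at 6 h (−0.524). With the epithelial covariate Gata3 (−0.41) and Smoc2 (−0.68) passed the threshold and Id1 (−0.32) did not. With the Y-linked covariate, chosen after seeing the data, all 3 lost the call (−0.47, −0.58 and −0.39), as the 3 genes then called included 0 of the 403. Their sizes kept most of those in the main fit. The Y-linked covariate fit takes the 6 h ratio at no Y-linked signal, which only replicate 1 came near. The lost calls therefore cannot show that male RNA caused the falls.

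Epithelial markers were lower at 6 h and higher at 12 h. A loess artefact is argued against by median centring, where the marker mean was −0.296 at 6 h and 0.346 at 12 h, against −0.254 and 0.293 with loess. At least 0.88 of the marker means was kept with median centring, the scanner's ratios or the series matrix. Whether the scanner's ratios and the series matrix rest on loess is not stated, so they cannot test it. The 27 markers moved together from replicate to replicate within groups (mean pairwise r = 0.55, highest of 1000 random lists 0.1), as a varying share of epithelium between dissected pools would give. The marker mean went the way of its time point in 5 of 7 replicates, so a response 1 way in every pool was not seen. It was 0.027 in 6 h replicate 4 and −0.055 in 12 h replicate 1. With 3 or 4 pools per time point, a response to DHT cannot be told apart from uneven dissection. Both may act together.

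Genes higher both at 12 h and in males (19, with medians of 0.42 and 0.72) could reflect tissue shares or androgen. With the muscle marker mean as covariate their 12 h median was 0.43, and with the epithelial one 0.39 (median SE 0.07 before and after). The genes were called at 12 h in part because their replicates agreed, and all 19 were above 0 in each. The marker means varied between those replicates, so a kept median was favoured by the choice of genes. The test therefore cannot decide about either tissue share. Both covariates ended every 12 h call in limma, in a fit with 1 residual degree of freedom fewer. The median was 0.37 in 12 h replicate 1, where muscle and epithelial means were 0.05 and −0.055, but a value above 0 there was also favoured by the choice. A response to androgen in both settings stays open: 9 of the 23 androgen-responsive genes were above 0 in both, where 8.5 were expected (Fisher's exact p = 0.685), and hybridisation day ran with the comparison.

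Some replicates lay far from the others in their group, in 9 of 138 groups of values tested; chance gives about 1 in 20, or 6.9. At 6 h Notch1 was −0.10 in replicate 3 (others −0.43 to −0.38) and Shh 0.12 in replicate 4 (others −0.45 to −0.38). Between the sexes replicate 1 had Errfi1 at 0.50 (others 0.74 to 0.80), Fkbp5 at 0.41 (0.76 to 0.81) and Xist at −4.99 (−5.91 to −5.82). Lyz2 was 0.02 in replicate 3 (others −0.77 to −0.59), Grem1 −0.25 in replicate 4 (−0.40 to −0.36), Srd5a2 0.80 in replicate 4 (0.34 to 0.41) and Hhip 0.38 in replicate 5 (0.18 to 0.22). Replicate 1 also held the array with 1646 outlier-marked spots.

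The 12 h and 6 h responses differed, by the test of the difference itself, in Mkx (1.09), Epha3 (0.99), Cbr2 (0.82), Wif1 (0.82), Col4a6 (0.81), Rhoj (−1.18), Pcdh8 (−0.43) and Mpv17l (−0.41), among the genes named by the rule. These genes were chosen for the size of the difference, and hybridisation day ran with the time point. Mkx, Epha3, Wif1 and Col4a6 were higher in males, so male RNA in the 6 h vehicle pools would also widen the difference for them. Limma called 0 genes for this difference without any 1 of the 12 h replicates, without 6 h replicate 2, and with the Y-linked or the epithelial covariate, with 2425 to 3485 at an unadjusted p under 0.05. Over 27 other settings Mpv17l lost its call in 16, Cbr2 in 15, Rhoj and Wif1 in 14 each, Mkx and Col4a6 in 11 each and Epha3 in 9, and Pcdh8 lost it in 12 of 26.

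Turning signs of whole replicates gave too few arrangements for a share under 0.05 within a comparison. At 6 h 1 of 8, the real one, gave as many as 403 genes and the highest other 0; at 12 h 1 of 4 gave 71 and the highest other 0; between the sexes 1 of 16 gave 1873 and the highest other 6. For the differences, the real split alone gave as many genes, a share under 0.05 each time, which argues against chance but does not exclude it. Of 35 splits of the 12 h and 6 h replicates 1 gave as many as 28, the highest other 4. Of 100 drawn from 126 splits of the male-female and 6 h replicates 1 gave 1709, the highest other 673. Of 56 splits of the male-female and 12 h replicates 1 gave 408, the highest other 1.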

How the results depend on the processing

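Of the alternatives, 5 were chosen after seeing the data: 6 h replicate 1 only, the Y-linked signal as covariate, the epithelial and the skeletal muscle marker means as covariates, and autosomal genes only. The others were fixed beforehand. Where no reason is given for a change, the cause was not tested.

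At 6 h, with 403 genes called, the count was 92 with median centring, 25 with the scanner's own ratios and 701 with the series matrix, of which 83, 24 and 396 were among the 403. It was 8 with the comparison fitted alone, where the spread rests on 4 replicates, and 1004 with array quality weights, which ran from 0.497 to 2.17. It was 1420 with all 24 arrays, a dye term and the pair as random effect, and 2660 with extraction day as random effect, whose correlation was −0.0537 and which counts the arrays of a pair as separate. It was 3784 with only arrays without dye swap and 3144 with only dye-swap arrays, where dye effects stay in the ratio by construction. The count was 1 with replicate 1 only, where 1 pair of pools is assumed to vary like the other groups, 3 with the Y-linked covariate and 9 with the epithelial covariate. Leaving out 1 replicate gave 13 to 234 (19 without replicate 1, 13 without replicate 2, 234 without replicate 3, 232 without replicate 4). The other settings stayed within 1.5 times 403.

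At 12 h, with 71 genes called, limma called 0 without background correction, with the series matrix, with the comparison fitted alone, and with either marker covariate, although 2636 to 3685 genes had an unadjusted p under 0.05. Leaving out 1 replicate gave 0 to 0, whichever of the 3 was left out, with 2899 to 2993 at an unadjusted p under 0.05. The count was 47 with the scanner's ratios, 21 with median centring, 15 with the strict filter, which tests fewer genes, 19 with marked spots kept and 113 with trend and robust. It was 293 with 24 arrays and a dye term, 2135 with extraction day, 3185 with only arrays without dye swap and 1344 with only dye-swap arrays.

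Between the sexes, with 1873 called, the count was 869 with the comparison fitted alone, 2826 with 24 arrays and a dye term, 5028 with extraction day, 3433 with only dye-swap arrays and 1038 with the epithelial covariate. Leaving out 1 replicate gave 1143 (replicate 4) to 1825.

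The difference between 12 h and 6 h (28 genes) was 11 without background correction, 74 with median centring, 92 with probes tested singly, 178 with weights, 693 with 24 arrays and a dye term, 2253 with extraction day, 50 with only arrays without dye swap, 434 with only dye-swap arrays and 3 with the muscle covariate. Limma called 0 with the scanner's ratios, with 6 h replicate 1 only, and with the Y-linked or the epithelial covariate, with 2425 to 2840 at an unadjusted p under 0.05. Leaving out 1 replicate gave 0 to 18. It was 6, 0, 13 and 18 without 6 h replicates 1, 2, 3 and 4, and 0 without any 1 of 12 h replicates 1, 2 and 3, with 2867 to 3485 at an unadjusted p under 0.05 where it was 0.

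The difference between the sexes and 6 h (1709) was 1110 with the scanner's ratios, 815 with median centring, 2914 with 24 arrays and a dye term, 4845 with extraction day, 83 with 6 h replicate 1 only, 148 with the Y-linked and 278 with the epithelial covariate. Leaving out 1 replicate gave 860 (6 h replicate 2) to 1817, with 969 without 6 h replicate 1. The difference between the sexes and 12 h (408) was 916 with 24 arrays and a dye term and 3056 with extraction day. Leaving out 1 replicate gave 135 (12 h replicate 1) to 428, with 202 without 12 h replicate 2 or replicate 3 and 254 without male-female replicate 4.

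The labels do not say that equal replicate numbers pair the comparisons. Over 10 pairs of replicates with the same number, 6 had a correlation above 0.1 across genes after group means were removed (−0.068 to 0.287), and 4 of 12 replicates correlated best with their own number. With the replicate number as a block, 155 genes differed between 12 h and 6 h, 1683 between the sexes and 6 h and 185 between the sexes and 12 h.

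Of the 30 list calls, 2 held with camera's estimated correlation (0 of 8 at 6 h, 0 of 10 at 12 h and 2 of 12 between the sexes, with 4, 2 and 7 lists at an unadjusted p under 0.05). The preset correlation does not hold for the 27 epithelial markers, whose mean pairwise r was 0.55, so their preset p values are too small. How far the other lists depart from the preset is not given. With fry, 12 list calls held, and 4, 2 and 11 lists passed. No background correction kept 28 calls, median centring 26, the scanner's ratios 29 and the series matrix 28, and 6 h replicate 1 only kept 4 of 8; none of these settings turned a direction.

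Genes called the same way at 6 h and 12 h (1) were 0 with median centring, the series matrix or 6 h replicate 1 only. Those at 6 h and between the sexes (33) were 13 with median centring, 53 with the series matrix and 0 with 6 h replicate 1 only, which called 1 gene in all, and r across genes (−0.207) was −0.092 with median centring and −0.071 with 6 h replicate 1 only. Those at 12 h and between the sexes (23) were 0 with the series matrix, which called 0 genes at 12 h in limma, and r (0.191) was 0.076 with median centring.

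Among named genes called at 6 h, 574 of 885 comparisons with another setting kept call and direction and 310 lost the call. At 12 h 203 of 437 kept it and 234 lost it, and between the sexes 1995 of 2108 kept it and 112 lost it. For the 3 differences, 113 of 215, 270 of 288 and 257 of 258 kept it. Among 9 always-named genes not called, other settings called one in 11 cases at 6 h and in 15 at 12 h. A direction turned in 2 cases. Eif2s3y at 6 h was 0.007 with the Y-linked covariate, which holds that gene itself, and Eif2s3x between the sexes was 0.25 with the mean of a gene's probes, which adds its other probes.

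Signal over background limits the dim genes. Spots near background give ratios pulled towards 0 by the offset, so Uty and Ddx3y in pools without clear signal carry only bounds, and 19 of the 71 calls at 12 h were in the dimmest quartile.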

Other observations

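The share of X-linked genes called between males and females was not shown to differ from that of autosomal genes. Of 630 X-linked genes 30 (4.76%) were higher and 35 (5.56%) lower in males, against 4.58% and 4.69% of 17361 autosomal genes (Fisher's exact p = 0.772 and 0.294, adjusted p = 0.926 and 0.441 over 6 tests). Outside Xist, lower RNA in males was seen in Pbdc1 and Ddx3x, which escape X inactivation, and in Eif2s3x by its brightest probe, but another of its probes read 1.14 and the mean of its probes 0.25, and Col4a5 and Col4a6, also X-linked, were higher in males by 0.72 and 0.87. These tests were added after the data were examined.

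Markers of neighbouring tissues were uneven between single pools. The mean of the intestine list was 0.541 in 6 h replicate 2 and at most 0.024 in the other 6 h replicates. The neuron and Schwann cell list had a mean of 0.389 in 6 h replicate 1, −0.461 in male-female replicate 3 and 0.214 in male-female replicate 5. Red blood cell markers had a mean of 0.762 in male-female replicate 3 and −0.37 in replicate 5, and skeletal muscle markers 1.363 in replicate 3 and −0.454 in replicate 2. Smooth muscle markers had a mean of −0.434 in male-female replicate 4, where fibroblast and mesenchyme markers were at −0.343.

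Several probes of a gene did not always read alike. Among called genes with another probe, 64 of 192 at 6 h, 5 of 20 at 12 h and 194 of 804 between the sexes had a probe of opposite sign, and a called probe of opposite sign was found in 0, 0 and 4 of them.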
